A study of Ambystoma mexicanum with 49 samples.

How the data were processed

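Poly(A) RNA of 49 single axolotl embryos from 17 stages and total RNA of 5 further libraries, 2 of stage 1 and 3 of stage 2, were analysed. Per the labels, RNA was extracted from single embryos, poly(A) libraries were read as paired 101-base reads and ribosome-depleted total RNA libraries as single 65-base reads, with 6 libraries per lane. Each poly(A) replicate is a separate embryo. Which embryos gave the total RNA libraries is not given in the sources used here. The deposited tables hold estimated counts per gene (RSEM expected counts, not normalized between libraries), 1 column per library. The deposited TPM tables hold the authors' own scaling of each library for its total and for gene length. RSEM 1.1.6 and Bowtie 0.12.1 are named in the submitters' processing notes, with no role or order. The reference they used is not given in the sources used here. Poly(A) and total RNA tables were tested apart from each other. Each table has 15631 genes, and 11354 of the names are symbols in the RefSeq table used here. Reads of near-identical members of a gene family, such as histones, keratins, myosins and globins, can be shared between members, so values of single members are uncertain.

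Poly(A) libraries held 12.0 to 44.9 M estimated counts and total RNA libraries 17.4 to 25.5 M. Over 51 pairs of libraries of the same stage and kind the lowest chi-square per degree of freedom was 5.70, so no pair was treated as a library deposited more than once. Columns of samples outside the labels numbered 0.

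Estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by stage, libraries were scaled by TMM, and all 17 stages were fitted together with stage as a factor by the quasi-likelihood method. Of 15631 genes 14437 were tested, and the genes left out held 0.00288% of the counts. The common dispersion was 0.0429. Each pair of stages was tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05. The SE of a log2 change is its size over the square root of F. There were 16 comparisons of neighbouring stages and longer ones of stage 8 with 1, 12 with 8 and 19 with 12, which with 24 against 19 and 40 against 24 made 5 main comparisons. A gene at 0 counts in a stage was given a lower bound on its fold, against a floor of 3 counts over the group. TPM are means with SD over libraries.

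The groups, tests, alternatives, 21 gene lists, panel of 20 genes and rule for named genes were fixed before the data were examined. That rule selects in each main comparison the 6 largest increases and 6 largest decreases among called genes with a symbol, a mean TPM of 10 or more in the higher stage and no overlap between the libraries of the stages. A share of 10% of genes has no overlap by chance with 3 libraries against 3. For other intervals it selects up to 2 each way. It also selects the 2 members with the smallest adjusted p from each list with 3 or more called members, and the report names only part of these list members. LOC names, 377 in all, were not named. The result of 1 gene was left out and is not reported here. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over all lists and main comparisons. Genes at 1 TPM or more were counted per library and compared by exact permutation. Log2 changes of stage 2 from stage 1 were correlated between the tables, with an interval of 95% from resampled genes.

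Alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, no filter, fits of only the 2 stages, the replicate number as a block, and each library left out in turn. The labels do not say whether replicate numbers link embryos across stages. For the lists fry and the estimated correlation were tried, for detected genes a minimum of 0.5, 2 or 5 TPM, and for the correlation between tables a mean of 50 or more counts in both.

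The calls were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The first setting tried gave every gene an assumed dispersion of 0.15. For 3 libraries against 3, as between stages 3 and 4, it recovered 7 of the 2-fold and 59 of the 4-fold changes with 1 false call, and for the total RNA design 6 and 44 with 3 false calls. After these results were seen a second setting was added, with dispersions estimated gene by gene from the data. It recovered 68 and 99 with 3 false calls, and 74 and 95 with 10 false calls for total RNA. The median dispersions of the second setting were 0.0372 and 0.0123. With camera 0 of 20 random lists of 30 genes were called, and a raised list was called. Genes were drawn independently of each other, so this check cannot show how camera does on lists whose members vary together.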

Results

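Poly(A) RNA was sequenced from 49 single axolotl (Ambystoma mexicanum, a salamander) embryos of 17 stages, from the fertilized egg at stage 1 to stage 40, shortly before hatching. There were 15 stages with 3 libraries each and 2 stages, 1 and 11, with 2 libraries each. The poly(A) libraries held 12.0 to 44.9 M estimated counts over 15631 genes. Another 5 libraries, 2 from stage 1 and 3 from stage 2, were made from total RNA after removal of ribosomal RNA and held 17.4 to 25.5 M estimated counts. Levels are TPM as mean ± SD. Log2 fold changes, given ± SE, come from counts scaled between libraries and can differ from ratios of TPM.

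The series asks when the embryonic transcriptome changes and when it stays stable, so neighbouring stages were compared first. Over 2000 genes changed at each of 6 intervals, and the edgeR quasi-likelihood test called at most 38 at any interval between stages 2 and 8. For the interval with 38, stage 5 to 6, the DESeq2 Wald test called 744 and DESeq2 size factors gave 159, with 2605 genes at an unadjusted p under 0.05. From stage 1 to stage 2, 3115 genes rose and 1609 fell. From stage 8 to 9 these numbers were 581 and 1704, from stage 11 to 12 they were 2357 and 3025, from stage 12 to 14 they were 3960 and 3590, and from stage 24 to 40 they were 5442 and 4460. Between stages 19 and 24, 1589 genes rose and 1889 fell. The edgeR quasi-likelihood test called 0 genes between stages 2 and 3 and 0 between stages 3 and 4, with 568 and 612 genes at an unadjusted p under 0.05. The DESeq2 Wald test called 25 and 3 genes there, 19 from stage 4 to 5, 16 from 6 to 7 and 49 from 7 to 8. With replicate 3 of stage 2 left out, 394 genes were called between stages 2 and 3, and with replicate 1 of stage 2 left out, 23 were called.

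**Figure D1:**
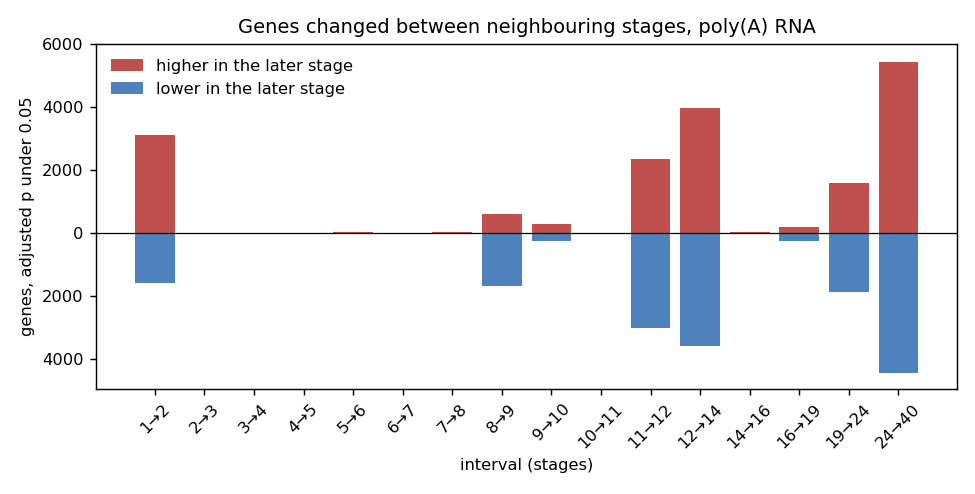
Bars give the number of genes with adjusted p under 0.05 between each pair of neighbouring stages (x axis), with genes higher in the later stage above 0 and genes lower in the later stage below 0 (y axis, number of genes). The tallest bars stand at stages 24 to 40, with 5442 genes higher and 4460 lower.

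**Figure D2:**
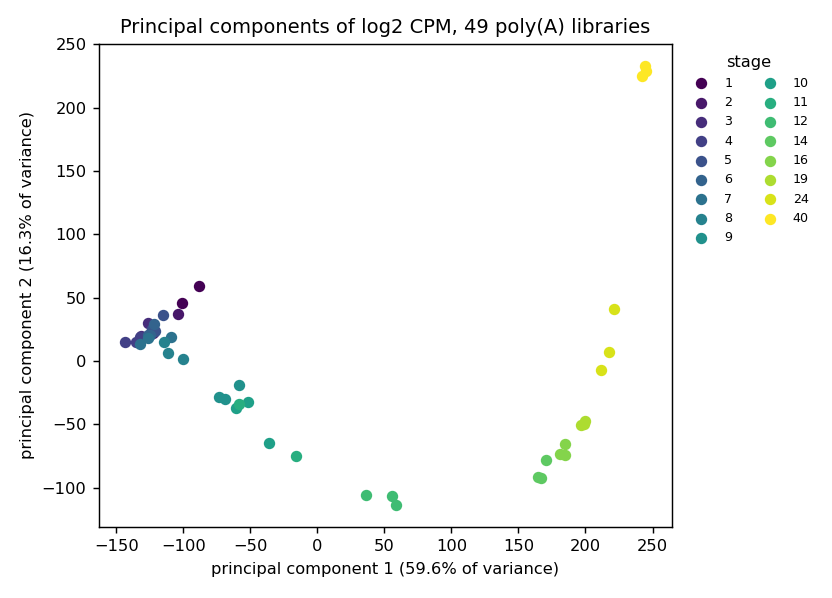
Each point is 1 of the 49 poly(A) libraries, coloured by stage and placed by its scores on the first component (x axis, 59.6% of the variance of scaled log2 counts) and the second (y axis, 16.3%). Libraries of stages 1 to 8 lie close together, and those of stage 40 lie farthest from them.

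CKM, a creatine kinase of muscle, was among the 2 genes called from stage 4 to 5, a call lost without replicate 2 of stage 4, at a log2 change of 2.48 against 2.65 with all libraries. From stage 5 to 6, 19 genes rose and 19 fell, against 31 and 128 with DESeq2 size factors, 17 and 28 with library size alone and 182 and 562 by the DESeq2 Wald test. ALAD, an enzyme of heme synthesis, fell from 78.8 ± 19.5 to 23.6 ± 4.79 TPM (SD, n = 3), a call lost without replicate 2 of stage 6, at a log2 change of -1.73 against -1.87 with all libraries. COPE fell 2.97-fold, LRRC56 rose 7.60-fold and ENO3, an enolase of muscle, 2.33-fold, and these calls were lost without replicate 1 of stage 6, at log2 changes of -1.36, 2.67 and 0.91. From stage 6 to 7, 4 rose and 2 fell. HIST1H2BC rose 6.21-fold, TXNIP fell 2.23-fold and STIL, a centriole protein, 1.65-fold, and these calls were lost without replicate 3 of stage 7, at log2 changes of 1.15, -0.99 and -0.52. From stage 7 to 8, 13 rose and 3 fell; NANOG, a pluripotency factor, rose from 7.52 ± 5.32 to 40.4 ± 36.4 TPM. UPK3B rose 9.07-fold, and PPP1R16B and C17orf59 fell 4.78-fold and 2.43-fold, calls lost without replicate 1 of stage 8, at log2 changes of 1.93, -2.05 and -1.03. From stage 14 to 16, 28 rose and 36 fell, against 28 and 13 with DESeq2 size factors. TMEM61, COLEC12, PARL and SLC25A1, a citrate carrier, had log2 changes of 2.25, 1.68, -0.88 and -0.87, and each call was lost with library size alone. Without replicate 2 of stage 16 the first 3 were not called, at 1.74, 1.54 and -0.76, and without replicate 1 of stage 16 SLC25A1 was not called, at -0.71. From stage 16 to 19, 181 rose and 268 fell, against 286 and 104 with DESeq2 size factors, 75 and 25 with library size alone and 389 and 161 by the DESeq2 Wald test, with GTSE1 up 2.89-fold and EGR4 down 8.26-fold. SLC13A1 rose 3.25-fold and FAM181B fell 2.13-fold, calls lost with library size alone, without replicate 1 of stage 16 at a log2 change of 1.42 and without replicate 3 of stage 16 at -0.84.

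The counts of these smaller intervals rested on single libraries. The 2 calls from stage 4 to 5 became 0 without any 1 library of stage 4, 1 without replicate 2 of stage 5 and 10 without replicate 3 of stage 5. The 38 calls from stage 5 to 6 became 0 without replicate 3 of stage 5 or replicate 1 or 2 of stage 6, 8 and 15 without replicates 1 and 2 of stage 5, and 354 without replicate 3 of stage 6. The 6 calls from stage 6 to 7 became 0 without replicate 1 or 3 of stage 6 or replicate 3 of stage 7, 1 without replicate 2 of stage 6 and 16 without replicate 1 of stage 7. The 16 calls from stage 7 to 8 became 0 without replicate 1 or 2 of stage 7 or replicate 1 of stage 8, 87 without replicate 3 of stage 7, and 9 and 39 without replicates 2 and 3 of stage 8. The call of NANOG was lost without replicate 1 of stage 8, at a log2 change of 1.37, and with library size alone, at 2.43. PPP1R16B was not called with library size alone either, at -2.25, nor C17orf59 with DESeq2 size factors, at -1.25, nor STIL from stage 6 to 7 with library size alone, at -0.68, or with no filter, at -0.72. All 4 of these counts became 0 when only the 2 stages were fitted. From stage 14 to 16 the 64 calls became 108, 10 and 29 without replicates 1, 2 and 3 of stage 14, 11, 2 and 28 without those of stage 16, and 0 with library size alone. From stage 16 to 19 the 449 calls became 193 and 80 without replicates 1 and 3 of stage 16 and 222, 201 and 237 without replicates 1, 2 and 3 of stage 19. EGR4 was not called without replicate 1 of stage 19, at a log2 change of -2.81, or with library size alone, at -2.95.

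A panel of 20 genes was followed over all stages. BTG4, an oocyte factor of the removal of maternal mRNA, stood at 2286 ± 221 TPM at stage 1 (SD, n = 2), 625 ± 116 at stage 8 and 3.73 ± 1.57 at stage 12 (SD, n = 3). MIXL1, a homeobox gene of mesoderm and endoderm, rose from 10.3 ± 7.14 TPM at stage 8 to 289 ± 72.5 at stage 9, a log2 change of 4.78. GSC, a gene of the gastrula organizer, rose from 0.136 ± 0.09 to 26.8 ± 12.2 TPM over the same interval and stood at 2.26 ± 0.71 at stage 12. T, the brachyury gene of mesoderm, was at 252 ± 49.3 TPM at stage 12. HOXA9 rose from 0.513 ± 0.29 TPM at stage 12 to 24.9 ± 4.03 at stage 14. HBE1, a globin gene of red blood cells, was at 928 ± 131 TPM at stage 40.

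**Figure D3:**
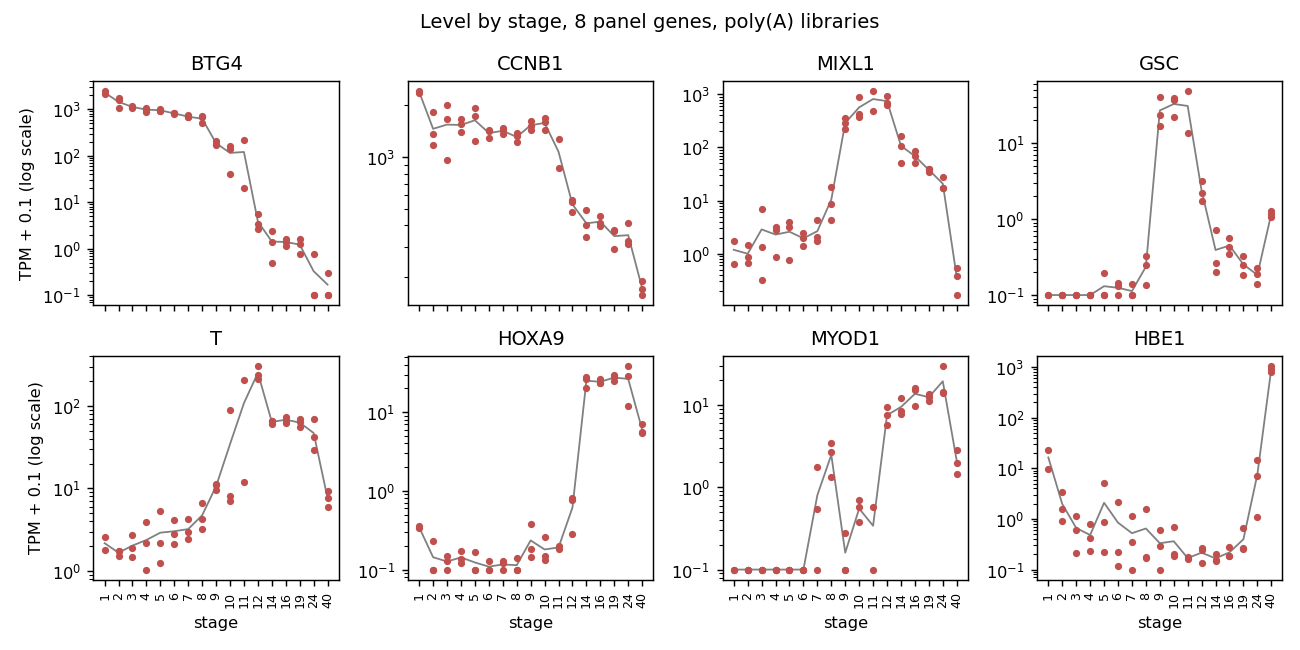
Points are single poly(A) libraries and lines join stage means of 8 panel genes over the 17 stages (x axis), as TPM + 0.1 on a log scale (y axis). BTG4 falls from 2286 TPM at stage 1 to 3.73 at stage 12, and HBE1 is at 928 TPM at stage 40.

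The comparison of stage 8 with stage 1 asks what changes during cleavage, before most embryonic genes are switched on. Ribosomal protein genes fell together, with 0 of 72 tested members higher and 70 lower and a median log2 change of -1.37; RPS26 fell from 102 ± 4.38 (SD, n = 2) to 43.6 ± 8.17 TPM (SD, n = 3). Of 50 genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, 44 were lower and 3 higher. Of 40 cell cycle genes, 24 fell and 11 rose, and CDK1, the main mitotic kinase, fell by 3.06 ± 0.24 on the log2 scale. Of 35 oocyte and germ plasm genes, 20 fell and 6 rose; TRIM36 fell by 2.29 ± 0.23 and ZP3, a coat protein of the egg, fell by 1.35 ± 0.15. Of 32 mesoderm and organizer genes, 14 rose and 2 fell, against 9 and 2 without replicate 1 of stage 1 and 10 and 1 without replicate 2.

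In total 4730 genes rose and 3915 fell between stages 1 and 8, a split that became 4016 and 4825 with DESeq2 size factors and 5150 and 2929 with library size alone; these scalings moved the median of all genes by -0.26 and 0.20 (log2). Among the 12 genes with the largest changes, ISY1, a splicing factor, rose from 0 to 38.4 ± 4.28 TPM, at least 416-fold against a floor of 3 counts over the group. FAM114A1, ZNF586 and C19orf25 rose at least 157-fold, at least 110-fold and at least 97.6-fold. ISY1 and C19orf25 were already called higher at stage 2. From stage 1 to 2 alone 4724 genes were called, against at most 38 at any interval between stages 2 and 8. Stage 8 was not tested against stage 2, and few calls per step do not show that levels stayed the same. In poly(A) RNA 1 of 71 ribosomal protein genes was lower at stage 2 than at stage 1 and 0 were higher. Of 50 oxidative phosphorylation genes 9 were lower and 0 higher. At stage 8 against stage 1, 70 of 72 and 44 of 50 were lower, and 0 and 3 higher. The genes called higher in poly(A) RNA from stage 1 to 2 had a median log2 change of 0.03 in total RNA. TNF, a cytokine, and HES2, a repressor of the Hes family, rose at least 29.5-fold and at least 28.4-fold. Histone genes went both ways, with 8 of 17 higher and 7 lower, 8 and 8 with DESeq2 size factors, and HIST1H2BC rose 146-fold. From stage 1 to 2 histones had 6 of 17 higher and 1 lower in poly(A) RNA, with a median log2 change of 0.34. In total RNA 0 were higher and 1 lower, with a median of -0.26. Histone changes in poly(A) RNA, here and at later stages, need not be changes in amount. DNAI1 and RFX2, genes of motile cilia, rose by 4.25 ± 0.47 and 1.83 ± 0.20 on the log2 scale, and 13 of 35 members of that list were higher and 8 lower, with a negative median under DESeq2 size factors. The stress response list had 12 of 31 members higher and 6 lower, with IER5 up 7.03-fold, and the poly(A) and mRNA turnover list had 10 of 37 higher and 18 lower, with a positive median under library size alone and with DCP2, an mRNA decapping enzyme, up 6.56-fold. Among neural genes 13 of 47 rose and 6 fell, with OTX1 up 13.0-fold, and among neural crest genes 6 of 27 rose and 6 fell, against 6 and 9 with DESeq2 size factors and 9 and 4 with library size alone. HOXD1 rose from 0 to 10.4 ± 2.37 TPM, at least 26.7-fold, and 4 of 36 Hox genes rose and 2 fell, against 2 and 3 with DESeq2 size factors. The largest adjusted p of the 12 genes with the largest changes was 0.00366 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

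From stage 1 to 8 CA2, a carbonic anhydrase, fell at least 63.0-fold to 0 TPM, and APOA1, the main protein of high-density lipoprotein, went from 53.5 ± 31.0 to 0.269 ± 0.31 TPM. KRT76, a keratin, fell 141-fold, POSTN, a matrix protein, 93.2-fold and LGALS2, a galectin, 70.3-fold; CASQ1, a calcium store protein of muscle, went from 10.5 ± 3.17 to 0.0642 ± 0.11 TPM. In the liver and gut list 0 of 42 genes rose and 31 fell, in the muscle list 4 of 42 rose and 22 fell, in the cartilage and matrix list 2 of 33 rose and 20 fell, and in the epidermis list 3 of 33 rose and 15 fell. A set of 264 late-stage genes was at 50 TPM or more at stage 40 and under 0.5 at stages 3 to 8. Summed over the set, the stage 1 libraries stood at 0.602% and 1.18% of the stage 40 level, with 234 and 251 of the genes detected. HBE1 was at 16.3 ± 9.21 TPM at stage 1 and 0.548 ± 0.82 at stage 8, and 166 of these 264 genes were lower at stage 8 than at stage 1, a direction that their choice by low levels at stages 3 to 8 favours. Without these genes, a choice made after seeing the data, 4730 genes rose and 3749 fell. Late-stage genes that missed the limits of the set stay in, so these are not counts free of late-stage signal. With replicate 2 of stage 1 left out, 18 liver and gut genes fell, and 1 lens and retina gene fell against 6 of 26 with both libraries. With replicate 1 of stage 1 left out, 3 neural crest, 2 stress response and 0 immune cell genes fell and 2 Hox genes rose. Heart, blood and immune cell genes had 6 of 21, 6 of 27 and 3 of 24 members lower, and 3, 4 and 2 higher, and with library size alone 1 immune cell gene was lower.

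The camera test with Benjamini-Hochberg adjustment called 8 lists in this comparison, with adjusted p = 3.79e-14 for ribosomal proteins, 4.04e-10 for oxidative phosphorylation, 0.000408 for liver and gut, 0.000674 for cartilage and matrix, 0.00189 for cell cycle, 0.0055 for muscle, 0.00651 for oocyte and germ plasm and 0.0225 for epidermis. In that order the values were adjusted p = 0.424, 0.312, 0.437, 0.277, 0.322, 0.401, 0.285 and 0.401 with an estimated correlation. Adjusted over the list alone, 45 oxidative phosphorylation and 32 liver and gut genes were lower, 11 neural genes were higher and 5 lower, 1 immune cell gene was higher and 0 lower, 2 Hox genes were higher and 1 lower, and 11 poly(A) and mRNA turnover genes were higher. Histones stood at 9 higher and 8 lower and lens and retina genes at 3 higher and 4 lower by that adjustment, and other lists here kept their numbers. Endoderm genes had 3 of 18 members higher and 1 lower, with a median of the other sign under library size alone.

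The comparison of stage 12 with stage 8 spans the start of embryonic transcription and gastrulation, when the germ layers form. Mesoderm and organizer genes had the highest median of the lists, with 27 of 32 higher and 3 lower and a median log2 change of 5.43. CER1, a secreted inhibitor of Nodal and BMP signals, rose from 0.587 ± 0.36 to 346 ± 78.8 TPM (SD, n = 3), and CDX1, a gene of posterior tissue, rose by 8.97 ± 0.41 on the log2 scale. Endoderm regulators GATA6 and CDX2 rose 786-fold and 518-fold, and 10 of 18 endoderm genes rose and 5 fell. GBX2 and OTX2, which pattern the neural plate, rose by 9.94 ± 0.58 and 8.98 ± 0.55. Oocyte and germ plasm genes had 13 of 35 higher and 13 lower, with a positive median that was negative with library size alone, where 0 were higher and 24 lower. Among the lower ones CPEB1, a regulator of poly(A) tails in the oocyte, fell 29.1-fold and FBXO43, a meiotic inhibitor, 60.3-fold.

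Of 14437 genes tested 4471 rose and 4547 fell between stages 8 and 12, against 4690 and 4419 with DESeq2 size factors. With library size alone 1383 rose and 8193 fell, and the median of all genes moved by -0.98 (log2). PRRT4, KRT24, MDK, MUC1 and TRPS1 rose at least 2458-fold, at least 1643-fold, at least 1321-fold, at least 1392-fold and at least 1004-fold. GJB6, a gap junction protein of epithelia, rose from 0.058 ± 0.06 to 336 ± 9.66 TPM. C19orf25 fell at least 136-fold, ANKRD37 355-fold, C9orf23 327-fold and KLF1, an erythroid factor in other vertebrates, 299-fold, while NR2C2 and TCF7 went from 14.9 ± 2.81 and 75.8 ± 8.64 TPM to 0.00848 ± 0.0147 and 0.137 ± 0.24. The largest adjusted p of these 12 genes was 0.000716 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

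Ribosomal protein genes rose in 71 of 72 cases, with RPL3 up by 3.20 ± 0.18 and RPL7A by 3.71 ± 0.22 on the log2 scale. Oxidative phosphorylation genes rose in 46 of 50 cases and none fell, with 17 higher and 7 lower under library size alone. Of 33 epidermis genes 22 rose and 4 fell, with KRT18, a keratin of simple epithelia, up 95.4-fold and TP63 down 5.65-fold. With library size alone 17 epidermis genes rose and 7 fell. Neural crest genes had 16 of 27 higher and 4 lower, with SNAI2 up 69.2-fold, and Hox genes had 15 of 36 higher and 1 lower. With library size alone these 2 lists had 14 higher and 8 lower, and 13 and 2. Motile cilia genes had 23 of 35 higher and 5 lower, with FOXJ1, the main regulator of motile cilia, up 6.44-fold, but 11 higher and 7 lower and a negative median with library size alone. Cell cycle genes had 21 of 40 higher and 7 lower, with MCM3, a replication helicase subunit, up 13.9-fold, but 10 higher and 25 lower with library size alone. Heart genes had 10 of 21 higher and 0 lower, muscle genes 16 of 42 higher and 3 lower, cartilage and matrix genes 13 of 33 higher and 3 lower, and lens and retina genes 3 of 26 higher and 1 lower. These 4 lists had, with library size alone, 6 higher and 4 lower, 8 and 6, 6 and 3, and 1 and 1.

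Poly(A) and mRNA turnover genes had 16 of 37 higher and 12 lower, neural genes 21 of 47 and 10, histones 8 of 17 and 4 and stress response genes 13 of 31 and 9, and each of these medians was positive here and negative with library size alone, where 5 were higher and 25 lower, 16 and 17, 5 and 6, and 9 and 13 in that order. Blood genes had 10 of 27 higher and 3 lower and liver and gut genes 10 of 42 and 1, with medians of 0 that were negative with library size alone, where 4 and 7 blood genes and 5 and 4 liver and gut genes were higher and lower, and immune cell genes had 8 of 24 higher and 0 lower, against 2 and 2 with library size alone. By camera with Benjamini-Hochberg adjustment, adjusted p = 2.68e-08 for mesoderm and organizer, 5.56e-34 for ribosomal proteins, 1.26e-12 for oxidative phosphorylation, 0.00136 for neural crest, 0.00382 for epidermis, 0.00456 for motile cilia, 0.00524 for cell cycle, 0.0135 for Hox genes, 0.0424 for muscle and 0.0446 for endoderm. In that order they were adjusted p = 0.106, 0.277, 0.278, 0.26, 0.312, 0.312, 0.401, 0.312, 0.516 and 0.283 with an estimated correlation. Adjusted over the list alone, 8 heart, 15 muscle, 9 blood, 7 immune cell, 9 liver and gut and 0 lens and retina genes were higher, 0 lens and retina genes were lower, 22 neural and 22 cell cycle genes were higher, 8 cell cycle and 5 epidermis genes were lower, and the other counts above were equal.

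The comparison of stage 19 with stage 12 asks what is switched on during neurulation. Hox genes, which pattern the body axis, rose in 28 of 36 cases and fell in 1, with a median log2 change of 4.66; HOXB8 rose from 0.596 ± 0.55 to 36.1 ± 6.10 TPM (SD, n = 3). SOX10, a neural crest regulator, rose by 9.02 ± 0.66 on the log2 scale, and PAX8 and NCAM1, a neural adhesion molecule, rose 41.6-fold and 21.4-fold. HAND1, a heart and mesoderm regulator, rose by 8.54 ± 0.49, and TAL1, a master regulator of blood formation, rose by 7.34 ± 0.56. POU5F1, a pluripotency factor, fell from 273 ± 36.4 to 1.91 ± 0.12 TPM, and CER1 fell 23.4-fold.

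Of 9431 genes called, 4737 rose and 4694 fell, and 5635 rose and 3513 fell with DESeq2 size factors, which moved the median of all genes by 0.28 (log2). With library size alone 4120 rose and 5192 fell, and the median moved by -0.17. TMEM61, PALM, GFI1, KRT6C, PRRX1 and SPIB, all at 0 counts at stage 12, rose at least 325-fold, at least 340-fold, at least 285-fold, at least 298-fold, at least 218-fold and at least 190-fold. C17orf39 fell at least 53.6-fold, SEBOX 62.4-fold and FOXD1 34.9-fold, and C14orf179 went from 53.5 ± 4.28 to 0.338 ± 0.59 TPM. The largest adjusted p of these genes, POU5F1 and CER1 was 0.000313 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Neural genes had 26 of 47 higher and 6 lower, heart genes 12 of 21 higher and 1 lower, cartilage and matrix genes 24 of 33 higher and 0 lower, and epidermis genes 22 of 33 higher and 2 lower, with TP63 up 8.78-fold. Ribosomal protein genes had 71 of 72 higher and oxidative phosphorylation genes 32 of 50 higher and 4 lower. Oocyte and germ plasm genes had 23 of 35 lower and 3 higher, with H1FOO, an oocyte linker histone, down 5.12-fold, and histones 10 of 17 lower and 3 higher. Mesoderm and organizer genes had 15 of 32 lower and 3 higher, with WNT11 down 6.92-fold. With DESeq2 size factors 15 oocyte and germ plasm, 6 histone and 12 mesoderm and organizer genes were lower, and 4, 3 and 6 were higher.

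Muscle genes had 17 of 42 higher and 3 lower, with MEF2C up 29.7-fold, neural crest genes 13 of 27 higher and 5 lower, blood genes 11 of 27 higher and 4 lower and liver and gut genes 14 of 42 higher and 3 lower, with VIL1, a protein of intestinal microvilli, up 143-fold. Stress response genes had 14 of 31 higher and 5 lower, with HSP90AA1 down 9.92-fold, immune cell genes 6 of 24 higher and 3 lower, and lens and retina genes 3 of 26 higher. Motile cilia genes had 10 of 35 higher and 10 lower, against 12 and 6 with DESeq2 size factors and 9 and 14 with library size alone. Cell cycle genes had 8 of 40 higher and 13 lower and endoderm genes 6 of 18 higher and 3 lower, with a median of the other sign under DESeq2 size factors, where 15 and 8 cell cycle and 7 and 2 endoderm genes were higher and lower, and poly(A) and mRNA turnover genes had 15 of 37 higher and 10 lower, with a median of the other sign under library size alone.

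For Hox genes camera with Benjamini-Hochberg adjustment gave adjusted p = 9.43e-08, and adjusted p = 0.0362 with an estimated correlation. The other calls were adjusted p = 1.3e-12 for ribosomal proteins, 0.00136 for neural, 0.00151 for cartilage and matrix, 0.00321 for oocyte and germ plasm, 0.00332 for epidermis, 0.00382 for oxidative phosphorylation and 0.00859 for heart. In that order they were adjusted p = 0.453, 0.106, 0.278, 0.278, 0.288, 0.622 and 0.177 with an estimated correlation. Adjusted over the list alone, 24 oocyte and germ plasm and 14 mesoderm and organizer genes were lower, 16 muscle, 13 liver and gut and 0 lens and retina genes were higher, and the other counts above were equal.

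The comparison of stage 24 with stage 19 asks what changes as the tail bud forms. Of 42 muscle genes 20 were higher and 0 lower, with a median log2 change of 1.75, or 1.62 with genes absent from a stage at their bound, and without replicate 3 of stage 24 12 were higher, with a median of 1.20. DES, the muscle intermediate filament, rose from 5.05 ± 0.47 to 40.6 ± 24.2 TPM (SD, n = 3), ATP2A1, a calcium pump of muscle, 3.98-fold and UNC45B, a myosin chaperone, by 4.91 ± 0.57 on the log2 scale. Cartilage and matrix genes had 14 of 33 higher and 0 lower, 8 and 0 without that library, with COL11A1 up 4.18-fold, and OGN, a matrix proteoglycan, rose 69.3-fold. HBZ, a globin, rose 6.87-fold, and blood genes had 6 of 27 higher and 1 lower. Cell cycle genes fell in 16 of 40 cases and rose in 1, with the replication licensing gene CDT1 down by 0.87 ± 0.10 on the log2 scale, and oocyte and germ plasm genes fell in 17 of 35 cases and rose in 1, with H1FOO down 2.46-fold. With library size alone 4 cell cycle and 9 oocyte and germ plasm genes were lower, with DESeq2 size factors 8 and 14, and without replicate 3 of stage 24 4 and 8.

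In this interval 1589 genes rose and 1889 fell, against 1895 and 1385 with DESeq2 size factors and 2168 and 723 with library size alone, which moved the median of all genes by 0.20 (log2). Without replicate 3 of stage 24, 1808 genes were called in place of 3478. That library scored 41.1 on the second principal component against -6.84 and 6.73 for replicates 1 and 2, and the median late-stage gene stood in it at 7.81% of its stage 40 level against 3.41% and 4.43%. TRIM72, KBTBD10 and FXYD2 rose 52.9-fold, 38.5-fold and 32.8-fold, and TMEM8C, a gene of muscle cell fusion, rose 39.8-fold but was not called by the DESeq2 Wald test, at a log2 change of 5.29. VGLL3, G0S2 and AQP3, a water channel, fell 12.5-fold, 5.00-fold and 4.75-fold. HES4, DOLK and HESX1 fell 3.35-fold, 3.16-fold and 3.12-fold, and their calls were lost without replicate 2 of stage 24, replicate 3 of stage 19 and replicate 3 of stage 24, at log2 changes of -1.51, -1.54 and -1.28. The call of HES4 was also lost with library size alone, at -1.53, and by the DESeq2 Wald test, at -1.68. HES4 had the largest adjusted p of the 12 genes with the largest changes, 0.0374 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

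Mesoderm and organizer genes had 7 of 32 lower and 0 higher, histones 8 of 17 lower and 0 higher, neural crest genes 3 of 27 lower and stress response genes 4 of 31 lower and 1 higher. With library size alone 4 mesoderm and organizer, 5 histone and 0 stress response genes were lower, and without replicate 3 of stage 24 3, 1 and 2 were, as was 1 neural crest gene. Without that library 2 neural, 2 epidermis, 1 immune cell, 1 liver and gut, 0 Hox and 0 lens and retina genes were higher and 3 poly(A) and mRNA turnover, 1 motile cilia, 0 endoderm and 0 oxidative phosphorylation genes were lower. Immune cell genes had 2 of 24 higher and 1 lower, endoderm genes 1 of 18 each way, liver and gut genes 2 of 42 higher and lens and retina genes 1 of 26 higher. Neural genes had 8 of 47 higher and 6 lower, epidermis genes 4 of 33 and 1, motile cilia genes 1 of 35 and 4, poly(A) and mRNA turnover genes 2 of 37 and 5, Hox genes 1 of 36 and 0 and oxidative phosphorylation genes 0 of 50 and 1, and in these 6 lists the median changed sign under library size alone, where 4 and 1 poly(A) and mRNA turnover, 1 and 1 motile cilia and 3 and 0 oxidative phosphorylation genes were higher and lower. With that scaling 0 endoderm genes were lower and 1 heart gene was higher. The edgeR quasi-likelihood test called 0 of 21 heart genes and 0 of 72 ribosomal protein genes.

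By camera with Benjamini-Hochberg adjustment the oocyte and germ plasm list had adjusted p = 1.47e-07, and adjusted p = 0.0362 with an estimated correlation. Other calls were adjusted p = 7.87e-09 for muscle, 0.000108 for cell cycle, 0.00136 for cartilage and matrix, 0.00136 for mesoderm and organizer, 0.00382 for blood and 0.0115 for histones. In that order they were adjusted p = 0.106, 0.278, 0.278, 0.312, 0.177 and 0.378 with an estimated correlation. Adjusted over the list alone, 21 oocyte and germ plasm, 18 cell cycle and 10 mesoderm and organizer genes were lower, 23 muscle, 15 cartilage and matrix, 9 neural, 3 epidermis, 0 Hox and 0 lens and retina genes were higher, 0 oxidative phosphorylation, 0 endoderm and 2 motile cilia genes were lower, 0 motile cilia genes were higher, and the other counts above were equal.

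The comparison of stage 40 with stage 24 asks what marks the differentiated embryo. Of 42 muscle genes 34 were higher and 5 lower, with a median log2 change of 5.02; TPM1, a tropomyosin, rose from 43.2 ± 6.59 to 1507 ± 260 TPM (SD, n = 3), and ATP2A1 40.3-fold. MYBPC3, a cardiac myosin binding protein, rose 124-fold, and 12 of 21 heart genes rose and 3 fell. Lens and retina genes rose in 25 of 26 cases, with a median of 5.90, or 5.17 with genes absent from a stage at their bound, and the lens crystallins CRYGB and CRYBA1 rose 148-fold and 280-fold. Liver and gut genes rose in 36 of 42 cases and fell in 1, with RBP4, the plasma carrier of retinol, up 95.4-fold. Cell cycle genes fell in 35 of 40 cases and rose in 0, with CDT1 down by 2.34 ± 0.11 on the log2 scale.

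In all, 5442 genes rose and 4460 fell, against 6842 and 2775 with library size alone, which moved the median of all genes by 0.42 (log2). MYH8, a skeletal myosin, rose from 0 to 289 ± 25.5 TPM, at least 752-fold, and MYH13, another myosin, from 0.0385 ± 0.07 to 222 ± 19.8 TPM. CTRB2, a pancreatic protease precursor, and GUCY1B3 rose at least 465-fold and at least 225-fold. AGXT, a liver enzyme, and APOA5, a liver apolipoprotein, rose at least 311-fold and at least 264-fold, though neither was called by the DESeq2 Wald test, at fitted log2 changes of 10.73 and 10.60, which are no bounds for genes at 0 counts. CDCP2, HOXB1 and KRT6C fell 175-fold, 127-fold and 116-fold. MSGN1, a presomitic mesoderm gene, fell 103-fold, SUV420H2, a histone methyltransferase, 97.4-fold and MIXL1 93.8-fold. The largest adjusted p of these 12 genes was 6.38e-06 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

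Cartilage and matrix genes had 31 of 33 higher and 2 lower, with TNC up 36.1-fold, and oxidative phosphorylation genes 30 of 50 higher and 3 lower, with SDHA up 2.44-fold. Blood genes had 13 of 27 higher and 5 lower, with HBZ up 12.9-fold, and immune cell genes 11 of 24 higher and 5 lower, with LCP1, a leukocyte actin bundler, up 149-fold. Oocyte and germ plasm genes had 25 of 35 lower and 2 higher, with MAEL and WEE2 down 24.7-fold and 67.4-fold, and mesoderm and organizer genes 24 of 32 lower and 2 higher. Motile cilia genes had 29 of 35 lower and 0 higher, with CCDC39 down 6.21-fold, Hox genes 19 of 36 lower and 2 higher, and histones 13 of 17 lower and 1 higher. Poly(A) and mRNA turnover genes had 24 of 37 lower and 4 higher and stress response genes 17 of 31 lower and 4 higher. Endoderm genes had 11 of 18 lower and 2 higher, with SOX17 down 117-fold. With library size alone these 3 lists had 17, 9 and 9 lower and 6, 5 and 2 higher. Neural genes had 12 of 47 higher and 24 lower, with SNAP25, a synaptic protein, up 99.5-fold and ZIC2 down 6.69-fold, and neural crest genes 5 of 27 higher and 16 lower, with the pigment genes DCT and TYRP1 up 11.7-fold and 8.98-fold. Epidermis genes had 7 of 33 higher and 11 lower, but 9 and 4 with library size alone, with COL17A1 up 211-fold. Ribosomal protein genes had 2 of 72 lower and 0 higher, and 4 higher and 0 lower with library size alone, where their median changed sign.

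By camera with Benjamini-Hochberg adjustment the calls that held were adjusted p = 4.16e-06 for lens and retina, 3.79e-12 for cell cycle and 1.22e-10 for oocyte and germ plasm, each at adjusted p = 0.0362 with an estimated correlation. The other calls were adjusted p = 3.57e-06 for muscle, 9.46e-06 for motile cilia, 1.03e-05 for cartilage and matrix, 5.83e-05 for mesoderm and organizer, 0.000317 for poly(A) and mRNA turnover, 0.000412 for liver and gut, 0.000763 for histones, 0.0073 for oxidative phosphorylation, 0.0111 for Hox genes and 0.0458 for endoderm. In that order they were adjusted p = 0.176, 0.14, 0.136, 0.278, 0.106, 0.446, 0.278, 0.648, 0.321 and 0.283 with an estimated correlation. Adjusted over the list alone, 26 lens and retina and 3 oocyte and germ plasm genes were higher, 10 epidermis and 0 ribosomal protein genes were lower, and the other counts above were equal.

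**Figure D4:**
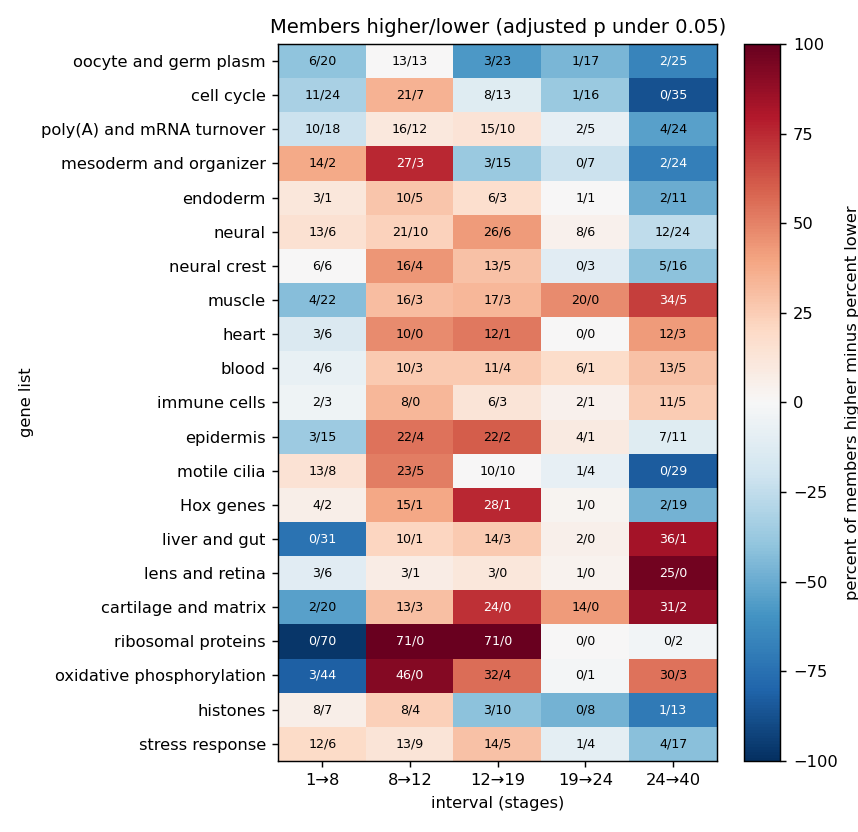
Each cell gives the members of a gene list (y axis) that were higher and lower with adjusted p under 0.05 in a main interval (x axis, stages), coloured by the percent of tested members higher minus the percent lower. Ribosomal protein genes had 70 members lower from stage 1 to 8 and 71 higher from stage 8 to 12 and again from 12 to 19; for stages 8 to 12, library size alone moved the median of all genes by -0.98 (log2), and with this shift some list medians went from above 0 to below 0 (oocyte and germ plasm, cell cycle, poly(A) and mRNA turnover, neural, motile cilia, histones and stress response).

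Neighbouring stages around the start of gastrulation were compared in turn. From stage 8 to 9, SLC12A3, a salt transporter, rose by 9.06 ± 0.43 on the log2 scale and CMTM8 249-fold, while ID4, an inhibitor of bHLH factors, fell 14.2-fold and C9orf23 19.2-fold. From stage 9 to 10, 264 genes rose and 273 fell, against 220 and 178 with library size alone. G0S2 rose 15.8-fold, and ANKRD37 rose by 3.05 ± 0.75 and KIAA0922 fell by 1.58 ± 0.34 on the log2 scale, calls lost without replicate 1 of stage 10, at 3.20 and -1.22. TREX2 fell 3.04-fold, a call lost without replicate 3 of stage 9, at a log2 change of -0.24. In this interval 21 genes were called without replicate 1 of stage 10, 824 without replicate 2 of stage 10, and 243 and 160 without replicates 1 and 2 of stage 9. From stage 10 to 11, 8 genes rose and 0 fell, MYC and NQO1 among them at 2.75-fold and 2.39-fold, and with library size alone NQO1 was not called, at a log2 change of 1.15. That count was 0 without replicate 3 of stage 11, where the calls of MYC and NQO1 were lost at log2 changes of 0.31 and 1.33, 1080 without replicate 2 of stage 11, and 162, 4 and 1 without replicates 1, 2 and 3 of stage 10. From stage 11 to 12, KRT24 and KRT73, keratins, rose at least 1019-fold and at least 193-fold, and ANKRD37 and CBLN1 fell 222-fold and 51.2-fold, calls lost without replicate 2 of stage 11, at log2 changes of -2.53 and -2.97. There 2483 genes were called without replicate 2 of stage 11 against 5382 with it. With library size alone 900 genes rose and 7218 fell there. From stage 12 to 14, GFI1 and KRT6C rose at least 329-fold and at least 114-fold and POU5F1 and SEBOX fell 18.6-fold and 38.4-fold. That split of 3960 and 3590 became 4525 and 2617 with DESeq2 size factors and 3030 and 4951 with library size alone. From stage 8 to 9 the split was 821 and 1419 with DESeq2 size factors.

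From stage 1 to stage 2, ISY1 and C19orf25 rose from 0 counts, at least 239-fold and at least 99.4-fold, and POSTN fell 37.0-fold. The call of C19orf25 was lost without replicate 1 of stage 1, at a fitted log2 change of 10.61, which is no bound for a gene at 0 counts. CPB1, a pancreatic carboxypeptidase, fell by 4.81 ± 1.61 on the log2 scale, a call lost without replicate 2 of stage 1, at -2.95, and by the DESeq2 Wald test, at -5.03. DESeq2 size factors gave 2686 higher and 2326 lower genes in this interval. Without replicate 1 of stage 1, 2978 genes were called, and 2635 without replicate 3 of stage 2, against 4724 with all libraries. When only the 2 stages were fitted 1109 were called, against 227 in the fit of the 5 total RNA libraries.

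The total RNA libraries ask whether a change in poly(A) RNA from stage 1 to 2 is also a change in the amount of RNA. In total RNA 165 genes rose and 62 fell of 11419 tested. SDAD1, named after its values were seen, rose from 37.2 ± 10.3 (SD, n = 2) to 184 ± 142 TPM (SD, n = 3) in poly(A) RNA and stood at 423 ± 12.9 and 394 ± 11.4 TPM in total RNA. HIST1H2AH and PDIK1L were also named after their values were seen. They rose by 2.65 ± 0.46 and 2.80 ± 0.31 on the log2 scale in poly(A) RNA. Their log2 changes in total RNA were -0.24 ± 0.10 and 0.11 ± 0.09. In poly(A) RNA they went from 24.4 ± 7.22 to 159 ± 138 TPM and from 17.35 ± 5.23 to 126 ± 93.9 TPM, so the stage 2 libraries differed widely. HIST1H2AH stood far higher in total RNA, at 2436.5 ± 279 and 2118.5 ± 283 TPM. TRAPPC10 rose in both, by 1.73 ± 0.33 in poly(A) RNA and 1.48 ± 0.19 in total RNA. APOA1 and TNNT3, a troponin of fast muscle, fell in both, and their log2 changes in total RNA were -5.31 ± 0.80 and -5.18 ± 0.71. CBFA2T2 rose by 4.52 ± 0.87 in total RNA and stood at 248 ± 50.9 and 269 ± 40.2 TPM in poly(A) RNA. Without replicate 3 of stage 2, 0 genes were called higher in total RNA, so the total RNA calls of TRAPPC10 and CBFA2T2 were lost.

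Across 11353 genes tested in both tables, which are not independent replicates, the log2 changes had a Pearson r of 0.259 (95% interval over genes 0.220 to 0.297) and a Spearman rho of 0.128. Both had permutation p = 0.0001, the smallest that the permutations run can give. Of 3061 genes called higher in poly(A) RNA 1718 (56.1%) had a positive log2 change in total RNA and 42 were called higher there, and of 1461 called lower 788 (53.9%) had a negative one and 46 were called lower. The medians of the 3061 genes were 1.21 in poly(A) RNA and 0.03 in total RNA on the log2 scale. Both tests called 127 genes, 88 in the same direction. In total RNA 13 of 24 muscle genes, 5 of 24 liver and gut genes and 5 of 21 cartilage and matrix genes fell, and these had 16, 13 and 8 members lower in poly(A) RNA. The total RNA count of 227 genes became 1 without replicate 3 of stage 2, 1545 without replicate 2 of stage 2, and 12 and 8 without replicate 1 and replicate 2 of stage 1. The few calls left without either stage 1 library were mostly of lower genes, unlike the split of 165 higher and 62 lower. Whether the log2 changes of the 227 called genes kept their direction was not examined. The genes higher in poly(A) RNA were chosen in the other table and cannot answer this. Their median total RNA change was 0.036 without replicate 1 of stage 1 and 0.030 without replicate 2, against 0.033 with all libraries.

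**Figure D5:**
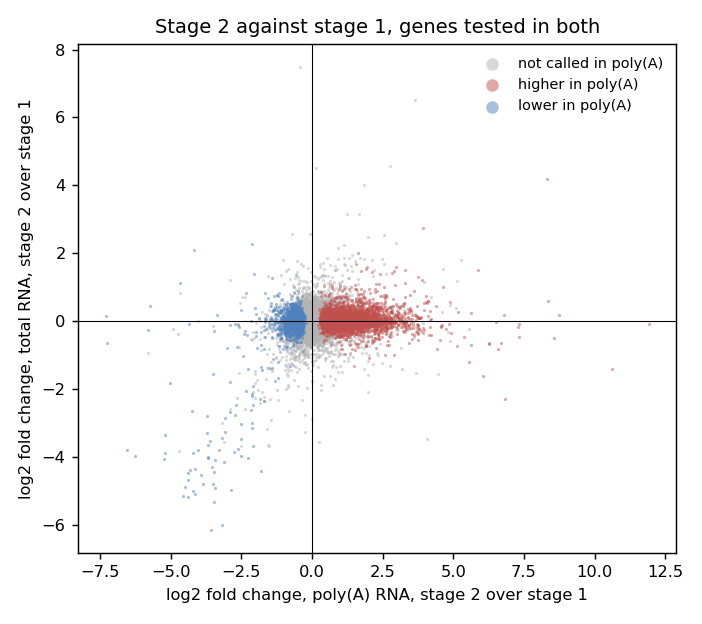
Each point is a gene tested in both tables, placed by its log2 fold change from stage 1 to 2 in poly(A) RNA (x axis) and in total RNA (y axis), coloured by its call in poly(A) RNA. The genes higher in poly(A) RNA lie along the horizontal axis, with a median of 1.21 in poly(A) RNA and 0.03 in total RNA.

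The number of genes at 1 TPM or more was 10540 ± 179 at stage 1 (SD, n = 2), 11471 ± 81.7 at stage 8, 10655 ± 41.1 at stage 12, 11414 ± 23.1 at stage 19, 11930 ± 239 at stage 24 and 13925 ± 93.3 at stage 40 (SD, n = 3). Each of the 5 differences between these stages in turn had exact two-sided permutation p = 0.1, the smallest that 3 libraries against 3 or 2 can give. At a minimum of 5 TPM the difference of stage 19 from stage 12 was 8.67 genes in place of 760, with exact permutation p = 0.9, and the other differences had exact permutation p = 0.1 at each minimum tried. The difference of stage 12 from stage 8 was -817 genes, and -496 and -1786 at 0.5 and 5 TPM. That of stage 8 from stage 1 was 932 genes, and 1515 at 5 TPM, and that of stage 40 from stage 24 was 1995 genes. The 50 genes with the highest counts took 16.6% ± 0.52 of the counts at stage 1, 38.7% ± 0.85 at stage 12 and 24.5% ± 1.39 at stage 40. The mitochondrial COX1 gene took 8.42% ± 0.48 of poly(A) counts at stage 1 (SD, n = 2) and 17.6% ± 2.83 at stage 2 (SD, n = 3), and 52.2% ± 0.47 and 48.5% ± 2.78 of total RNA counts. How mitochondrial genes entered the reference is not given in the sources used here, so what these shares cover is uncertain.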

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

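Leaving out the late-stage genes, using each stage 1 library alone for the lists at stage 8 against stage 1 and leaving replicate 3 of stage 24 out of the lists at stage 24 against 19 were chosen after the data were seen, and the other alternatives were planned. Where a result changed, the cause was not tested.

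When only the 2 stages were fitted, the genes called numbered 1109 from stage 1 to 2, 0 from 4 to 5, 0 from 5 to 6, 0 from 6 to 7, 0 from 7 to 8, 4157 from 8 to 9, 2 from 9 to 10, 0 from 10 to 11, 3235 from 11 to 12, 0 from 14 to 16, 68 from 16 to 19 and 1942 from 19 to 24. With library size alone they numbered 2 from stage 2 to 3, 5 from 10 to 11, 8118 from 11 to 12, 0 from 14 to 16 and 100 from 16 to 19, and from stage 8 to 12 there were 1383 higher and 8193 lower. There DDX4 changed direction, to a log2 change of -0.0665. The DESeq2 Wald test called 25 from stage 2 to 3, 3 from 3 to 4, 19 from 4 to 5, 744 from 5 to 6, 16 from 6 to 7, 49 from 7 to 8 and 23 from 10 to 11. DESeq2 size factors gave 159 from stage 5 to 6 and 41 from 14 to 16. A replicate block gave 2 from stage 6 to 7, 7 from 7 to 8 and 28 in total RNA, 8 higher and 20 lower. With it NANOG, PPP1R16B and C17orf59 from stage 7 to 8 and TXNIP and STIL from 6 to 7 were not called, at log2 changes of 2.25, -2.24, -1.24, -1.15 and -0.71. Over 45 pairs of libraries with the same number in neighbouring stages the correlation of residuals had a median of 0.0243 (-0.196 to 0.354). Pairs with unlike numbers had a median of -0.00889. In 24 of the 45 cases the best match in the next stage had the same number. A link between libraries of the same number is therefore not excluded.

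With each library left out in turn, the counts ranged from 2635 to 5478 for stage 1 to 2, 0 to 394 for 2 to 3, 0 to 10 for 4 to 5, 0 to 354 for 5 to 6, 0 to 16 for 6 to 7, 0 to 87 for 7 to 8, 21 to 824 for 9 to 10, 0 to 1080 for 10 to 11, 2483 to 5995 for 11 to 12, 2 to 108 for 14 to 16, 80 to 387 for 16 to 19, 1808 to 3751 for 19 to 24 and 1 to 1545 for total RNA. Where 1 library was left in a stage, it was assumed to vary like the other stages.

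Of 105 list tests camera called 46, 5 with an estimated correlation, and fry called 81. At minimums of 0.5, 2 and 5 TPM the difference in detected genes was 720, 1149 and 1515 for stage 8 less stage 1, -496, -1158 and -1786 for 12 less 8, and 856, 536 and 8.67 for 19 less 12. For stage 40 less stage 24 it was 1717 at 0.5 TPM. The Pearson r between tables was 0.207 over genes with a mean of 50 or more counts. Of 388 results of named genes, 380 kept their call and direction with DESeq2 size factors, 365 with library size alone, 372 by the DESeq2 Wald test, 387 with no filter, 340 in fits of the 2 stages (10 gave no value), 378 with a replicate block and 328 with every library left out in turn.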

Other observations

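The panel genes CCNA1 and CHRD moved in opposite directions from stage 8 to 12. CCNA1, the cyclin A of germ cells and early embryos, went from 421 ± 7.98 TPM at stage 1 (SD, n = 2) to 27.1 ± 2.47 at stage 9 (SD, n = 3), and its log2 change from stage 8 to 12 was -6.39 ± 0.44. CHRD, an inhibitor of BMP signals, rose by 6.80 ± 0.55 on the log2 scale to 279 ± 24.4 TPM at stage 12 (SD, n = 3). SOX2, a neural and pluripotency factor, fell by 2.27 ± 0.18 from stage 24 to 40. ACTC1, a cardiac actin, rose by 2.19 ± 0.24 on the log2 scale over that interval to 669 ± 30.6 TPM (SD, n = 3). DAZL, a germ cell RNA-binding protein, stood at 36.1 ± 2.60 TPM at stage 1 (SD, n = 2) and 0.331 ± 0.091 at stage 40 (SD, n = 3).

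Both tests of the spread at stages 10 and 11 were chosen after the result was seen, and so was the reading of the 2 tests of a gain of poly(A). The tests of late-stage genes were set after the stage means of HBE1, POSTN and CPB1 were seen and before the values of the whole set.

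Poly(A) RNA had 3115 genes higher at stage 2 than stage 1 and total RNA 165. The median change of the higher genes in total RNA was 0.0271 of that in poly(A) RNA (95% interval over genes 0.0192 to 0.0355). It ranged from 0.0202 to 0.0376 with each total RNA library left out. Choosing genes for rising in poly(A) RNA lowers this ratio by an amount not estimated. So low a ratio still argues against lower power of the total RNA libraries as the only source. After thinning stage 2 to the depth of the shallower stage 1 library 3084 genes were higher. This was a ratio of 0.990 to 3115, with 3045 genes in both. The stage 2 libraries held 15.5 to 23.3 M counts and were thinned to 14.5 M, so this argues only against that difference in depth. A candidate explanation is that RNA present at stage 1 gains poly(A): the poly(A) to total RNA ratio in 1 stage 1 library had a Spearman rho of -0.591 with the rise from the other (-0.647 in the other order, 10567 genes), and the log2 ratio of 2837 higher genes less that of 6281 uncalled genes was -2.09 (-2.16 to -2.01) at stage 1 and -1.003 (-1.05 to -0.953) at stage 2. The ratio difference was taken over genes chosen for rising in poly(A) RNA and decides nothing, and with poly(A) libraries of stages 3 and 4 set against the stage 1 total RNA, where the edgeR test called 0 genes (612 at an unadjusted p under 0.05, 3 by the DESeq2 Wald test), rho was -0.228 and -0.274, past the bound of -0.2 that was set. A gain of poly(A) and a difference in poly(A) selection between libraries of the 2 stages both stay open.

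Over 264 late-stage genes, chosen for levels under 0.5 TPM at stages 3 to 8, the summed level of the stage 1 libraries was 0.602% and 1.18% of that at stage 40, with gene medians of 0.441% and 0.941% and 234 and 251 genes detected. RNA or reads of late embryos could be the source, but the rho with stage 40 levels, 0.487 and 0.578, lay between the bounds set, so this stays open. In total RNA 229 of them were higher at stage 1 than stage 2 and 25 lower, with a median log2 difference of 1.32, which goes with a source already in the RNA of stage 1 embryos, and whether maternal or from other tissue was not tested. Replicate 2 of stage 2 stood at 0.788%, with a rho of 0.0738. The signal was not confined to stage 1. Replicate 3 of stage 5 had 220 of the genes detected, a summed level of 0.290% and a rho of 0.412. Replicate 2 of stage 5 had 158 detected and a rho of 0.325. The other libraries of stages 3 to 8 had 63 to 162 detected and a rho of at most 0.233. In stages 3, 5, 6, 7 and 8 replicate 3 had the most genes detected, with 161, 220, 159, 162 and 140. The other replicates of these stages had at most 120, 158, 109, 90 and 113. In stage 4 replicate 2 had the most, with 93. Whether libraries share a source apart from their stage, by replicate number or singly, was not tested.

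On an axis from the mean of stage 9 to that of stage 12, replicates 1, 2 and 3 of stage 10 lay at 0.359, 0.104 and 0.145 and replicates 2 and 3 of stage 11 at 0.0938 and 0.506. Replicate 1 of stage 10 lay 0.614 of the way from the other stage 10 libraries to replicate 3 of stage 11, so replicate 1 of stage 10 and replicate 2 of stage 11 may carry each other's stage. Embryos of 1 stage may also have differed in progress: the difference between the stage 11 libraries followed that of stage 12 from stage 9 with a rho of 0.601, and that of replicate 1 of stage 10 from the others with 0.573. Both stay open, and no fit with exchanged stages was run.

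Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Each split other than the real one mixes the 2 stages in both groups, so a difference between stages widens its spread and lowers its calls. Where the real split called 0, every split gave as many by definition, so that result decides nothing. Fitted with the 2 stages alone, the real split called 4157 genes from stage 8 to 9, 2 from 9 to 10, 7064 from 12 to 14, 68 from 16 to 19, 1942 from 19 to 24, 10094 from 24 to 40, 9408 from 8 to 12 and 9177 from 12 to 19, and the highest other split 0, 0, 0, 1, 1, 0, 0 and 0, so 1 of the 10 splits gave as many in each. From stage 2 to 3, 3 to 4, 4 to 5, 5 to 6, 6 to 7, 7 to 8 and 14 to 16 the real split called 0, the highest other 0, 0, 2, 16, 2, 1 and 3, and 10 of the 10 gave as many.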
